A study of Felis catus with 6 samples.

How the data were processed

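Total RNA of F81 feline kidney cells was depleted of ribosomal RNA with the Ribo-Zero Magnetic Gold kit and made into stranded total-RNA libraries, according to the labels, with reads of 150 nt from both ends and an average insert of 300 bp. The labels give 3 flasks infected with FPV and 3 uninfected flasks, collected at 48 h, and groups were taken from the sample titles. The submitters name HISAT, StringTie and edgeR without versions, roles or settings. The genome build, the annotation and the rules by which transcripts were kept as long non-coding RNA are not stated in the sources used here.

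The values are FPKM made by the authors, 1 column per library with no pooling, and no scaling between libraries is recorded. All 6 columns were mapped to a sample by their header, and 0 were left unmapped. Rows carry an assembly identifier and a 1-letter class code, read here by the letters' usual meaning in transcript comparison tools: intergenic (u), intronic (i), antisense exonic overlap (x), other exonic overlap (o) and a shared splice junction (j). The table holds assembled long non-coding transcripts only, so its sums are parts of each library and not its depth. Low values were searched for steps of whole reads. Over the pairs of libraries, 8 to 61 transcripts lay on the step found, out of 17691 to 39344 above 0.01 FPKM in both. Reads were therefore not recovered, the depth is unknown, and no count test, counting interval or detection floor was used.

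Transcripts with the same locus number were summed, giving 89492 loci, of which 88991 had 1 transcript and 120 had several codes. Loci with a mean of at least 0.5 FPKM over the 6 libraries were tested, 51531 in all. Values were taken as log2(FPKM + 0.1) and fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust) on the group alone, FPV minus Ctrl, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A second count required an absolute log2 fold change of at least 1. Positional classes were tested with camera at a correlation of 0.01, with an estimated correlation beside it. Measures with 1 value per library were compared by exact permutation in scipy 1.17.1, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. All p-values concern these 6 flasks of 1 cell line. Those of limma also rest on a variance borrowed from other loci, so they do not measure the spread of a locus between flasks alone.

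The test was tried on simulated data made by shuffling the residuals of these libraries among loci of like abundance. The 6 libraries were also reordered at each locus on its own, which removes differences shared by whole libraries. With no change added, 10 draws gave 4 to 13 called loci, where a test that held its threshold would mostly give none. Of 50 loci each changed by 1, 2, 4 and 6 on the log2 scale, it called 2%, 0%, 26% and 32%, beside 15 false calls. Loci were raised or lowered and values cut at 0 FPKM, so many lowered loci changed by less than the size added. The median fitted changes were 1, 1.48, 3.02 and 3.36, so the shares called are not those of changes reached in full.

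The design, the alternatives and the rule for named loci were fixed before the data were examined. That rule takes the 5 loci with the largest positive and the 5 with the largest negative log2 fold change among those past the threshold with a mean of at least 1 FPKM and groups that do not overlap. As the table pairs no identifier with a gene, 2 identifiers are printed per direction. Loci described by abundance, by their number in the assembly or by how many alternatives called them were chosen after their values were seen.

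The comparison of protein-coding genes, the test of gene lists, the cell type markers and the value of the transferrin receptor TFRC, through which parvoviruses of carnivores enter cells, had been planned and could not be computed. The table holds no coding gene, and 0 of its identifiers matched the reference table of feline genes.

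Alternatives chosen beforehand were pseudocounts of 1 and 0.01 FPKM, no filter, a mean of at least 2 FPKM, median-of-ratios and upper-quartile factors, limma without trend and robust, each transcript on its own, the replicate number as a block, and each library left out in turn. Added after the data were seen were limma without robust alone, estimated library weights, factors computed on loci of at least 10 FPKM, FPV-3 and Ctrl-1 left out together, and other limits for abundance, detection and dominant loci.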

Results

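Long non-coding RNA was measured in F81 cells, a feline kidney cell line, 48 h after infection with feline panleukopenia virus (FPV), a small parvovirus with a DNA genome, and in uninfected cells (Ctrl). Each group held 3 flasks with 1 library per flask, so n = 3 per group. The deposited values are FPKM for 90588 assembled transcripts at 89492 loci, without gene names, coordinates or coding genes. Intergenic transcripts made up 52.7% (47757) and intronic transcripts 45.3% (41045) of the table. A further 861 shared a splice junction with a reference gene, 657 lay antisense to one and 268 overlapped its exons in another way. Only 10937 transcripts (12.1%) were above 0 in all 6 libraries, and 17712 were above 0 in a single library. The sequencing depth of the libraries is unknown, because the file holds no counts.

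The libraries differed in how many transcripts they listed and at what level. Between 48954 and 51189 transcripts were above 0 in the Ctrl libraries, against 51210 in FPV-1, 56512 in FPV-2 and 34632 in FPV-3. The median FPKM of the transcripts above 0 was 1.75, 0.794 and 0.517 in Ctrl-1 to Ctrl-3, 1.45 in FPV-1, 0.236 in FPV-2 and 3.45 in FPV-3. Across the 51531 loci with a mean of at least 0.5 FPKM, Spearman's rho was 0.24 to 0.498 between Ctrl libraries, 0.352 between FPV-1 and FPV-2, −0.232 between FPV-1 and FPV-3, and −0.0569 between FPV-2 and FPV-3. Between groups it ran from −0.407 (Ctrl-1 and FPV-3) to 0.434 (Ctrl-3 and FPV-2). A locus listed in few libraries can reach that mean, which can lower rho. Among the 146 loci with a mean of at least 10 FPKM it was 0.653 to 0.91 within groups and 0.643 to 0.836 between groups. These correlations are across loci, which are not independent replicates.

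**Figure D1:**
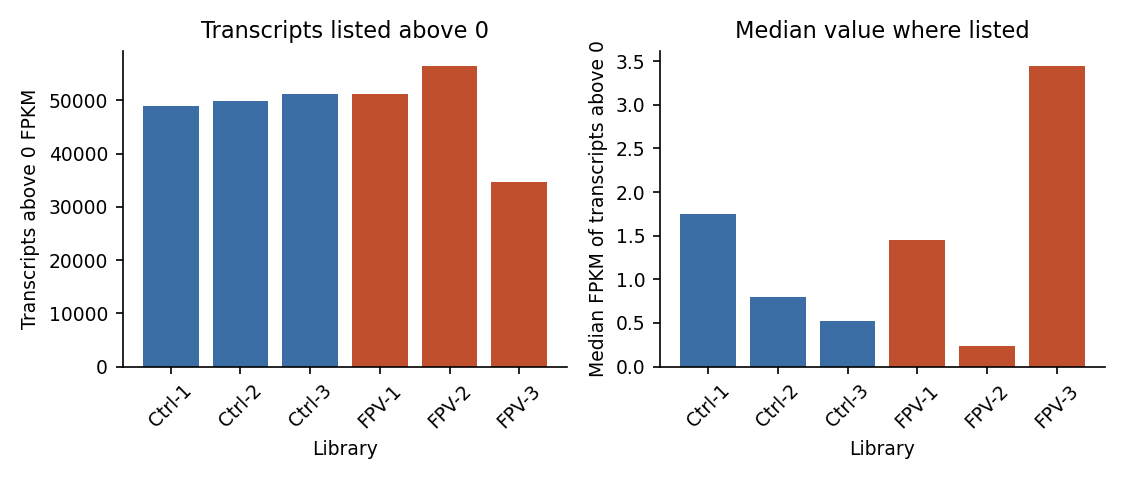
Number of transcripts above 0 FPKM (left) and median FPKM of those transcripts (right) in each library, with Ctrl in blue and FPV in red and 1 bar per library. FPV-3 listed the fewest transcripts (34632) at the highest median (3.45 FPKM), and FPV-2 the most (56512) at the lowest median (0.236 FPKM).

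The comparison of infected with uninfected cells asks which RNAs change with FPV infection; the series title places it in the study of the immune response. Of 51531 loci tested, 15 were called higher and 14 lower in infected cells, 29 in all, where 10 simulated draws of the same size without a change gave 4 to 13. A test that held its threshold would give no call in most such draws. The adjusted p-values of limma were therefore too small on the simulated data, and may be too small here. Those draws hold no differences shared by whole libraries, so they cannot separate an effect of infection from such differences. Of the 15 called higher, 9 stood below 2 FPKM in every Ctrl library, and 7 of the 15 were intronic and 7 intergenic. Of the 14 called lower, 9 were intergenic, 2 carried several positional codes, and 1 each was intronic, antisense or sharing a junction. The FPV values lay entirely on 1 side of the Ctrl values at 24 of the 29 loci (11 higher, 13 lower), and 22 changed by at least 1 on the log2 scale. The loci were called on these same values, so neither count is separate support. The test was limma on log2(FPKM + 0.1), two-sided, with Benjamini-Hochberg adjustment at 0.05, a scale that understates the change of low loci. At an unadjusted p under 0.05, 1227 loci were higher and 1519 lower, together 5.33% of those tested. The simulated draws without a change gave 4.62% to 4.87%, with the same limit.

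The count was 10, 12 and 10 without Ctrl-1, Ctrl-2 and Ctrl-3, and 16, 59 and 117 without FPV-1, FPV-2 and FPV-3. The model moved both the count and its balance, to 37 higher and 10 lower with median-of-ratios scaling, 3 and 0 with upper-quartile scaling, 11 and 30 with a pseudocount of 0.01 FPKM, 2 and 0 with a pseudocount of 1 FPKM, 453 and 2361 with estimated library weights, and 0 with limma's trend and robust options off (1330 higher and 2104 lower at an unadjusted p under 0.05).

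The deposited table does not pair its identifiers with gene names, so 4 loci are named and the others described by class. The intronic locus MSTRG.80310 rose from 0, 0.404 and 0 FPKM in Ctrl-1 to Ctrl-3 to 7.37, 16.6 and 11.5 FPKM in FPV-1 to FPV-3, by 6.04 (SE 0.978) on the log2 scale with an adjusted p of 8.15e-06 in limma. The intergenic locus MSTRG.119961 was listed at 0 in every Ctrl library and at 7.70, 20.1 and 1.06 FPKM in the FPV libraries (limma adjusted p = 0.024). In the other direction, the intergenic locus MSTRG.136072 stood at 4.62, 9.64 and 7.32 FPKM in Ctrl and 3.36, 0 and 0.126 FPKM in FPV, a change of −4.03 (SE 0.876) with an adjusted p of 0.0129 in limma. The antisense locus MSTRG.14336 went from 6.62, 4.83 and 9.34 FPKM to 1.65, 0 and 0.975 FPKM, a change of −3.57 (SE 0.82) with an adjusted p of 0.0293 in limma. The calls on MSTRG.80310 ended without FPV-2 (adjusted p = 0.0813; 1.05e-23 to 0.649 over its alternatives). Those on MSTRG.119961 ended without Ctrl-2, Ctrl-3, FPV-1 or FPV-2, those on MSTRG.136072 without any 1 of the Ctrl libraries or FPV-3, and those on MSTRG.14336 without any 1 of the Ctrl libraries or FPV-1. Without FPV-2 the log2 fold changes of MSTRG.136072 and MSTRG.14336 were −2.98 and −2.31, and pseudocounts of 1 and 0.01 FPKM gave 3.45 and 8.34 for MSTRG.80310, −2.22 and −5.37 for MSTRG.136072 and −2.15 and −4.72 for MSTRG.14336.

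The next 3 loci of the same rule that rose were intergenic, with log2 fold changes of 5.34, 5.06 and 4.74, and each had at least 1 Ctrl library listed at 0. These became 2.66, 2.70 and 2.53 with a pseudocount of 1 FPKM and 7.72, 6.58 and 6.31 with 0.01 FPKM. Their calls held in 0, 1 and 0 of the fits that left out 1 library. The next 3 that fell were an intergenic locus (−3.46), a locus sharing a junction (−3.25) and an intronic locus. The calls on the intergenic and the junction locus held in 1 leave-out fit each, and without FPV-1 their changes were −2.43 and −1.56. The intronic locus fell from 24.8 ± 4.53 to 5.66 ± 3.47 FPKM (SD, n = 3 each), by −2.28 on the log2 scale with an adjusted p of 8.15e-06 in limma. Singled out after their values were seen, 7 loci were called in at least 10 of 19 alternatives, 4 higher and 3 lower, and 0 were called in every fit that left out 1 library. Besides MSTRG.80310, the 4 higher ones were an intronic locus that went from 0.531 ± 0.621 to 9.91 ± 0.736 FPKM (log2 fold change 4.51), an intergenic locus from 0.844 ± 0.66 to 12.9 ± 3.34 FPKM (4.18), and an intergenic locus at 0, 1.05 and 1.87 FPKM in Ctrl and 5.65, 18.5 and 12.5 FPKM in FPV.

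**Figure D2:**
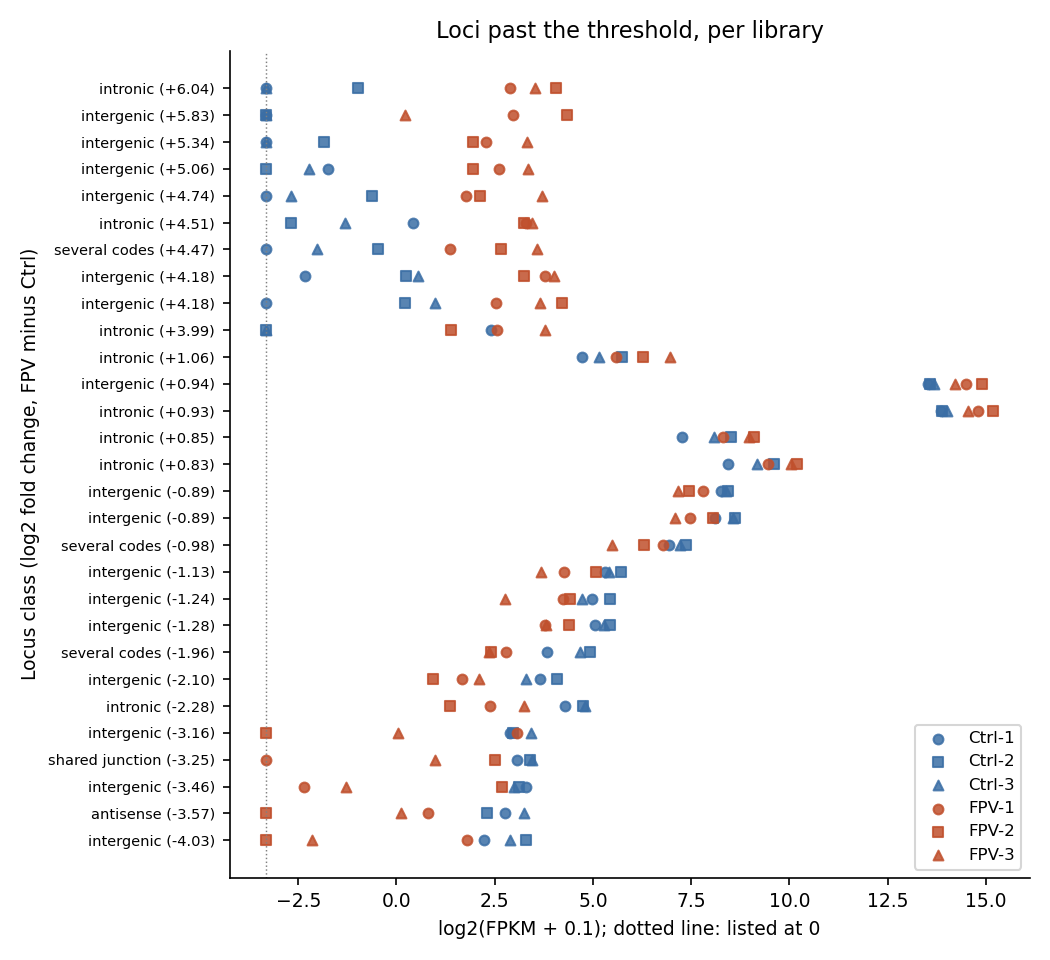
Values of the 29 loci past the threshold on a log2(FPKM + 0.1) axis, 1 point per library, Ctrl in blue and FPV in red, ordered by log2 fold change and labelled with their positional class. The FPV points do not overlap the Ctrl points at 24 of the 29 loci, which were called on these same values. At 12 loci at least 1 library was listed at 0 (dotted line).

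The most abundant loci carried a large part of the summed FPKM, and the first 3 had higher means in infected cells. The top locus, intergenic, held 23.5% to 35.8% of the sum in the Ctrl libraries and 33.9%, 55.9% and 30.1% in FPV-1 to FPV-3. Its level was 61794 ± 11520 FPKM in Ctrl and 136123 ± 69600 FPKM in FPV (SD, n = 3 each), a ratio of 2.20 that did not pass the limma test (adjusted p = 0.721). The second locus, intronic, was at 15426 ± 824 FPKM in Ctrl and 29819 ± 6933 FPKM in FPV, a ratio of 1.93 (limma adjusted p = 2.53e-23). The third, intergenic, was at 12354 ± 671 and 24201 ± 5732 FPKM, a ratio of 1.96 (limma adjusted p = 7.15e-23). An exact two-sided permutation test gave p = 0.1 for each, the smallest possible with 3 against 3. Both calls held in 9 of 19 alternatives and ended without FPV-2 (adjusted p = 0.62), where the log2 fold changes of 0.93 and 0.94 became 0.75 and 0.77. With those fold changes unmoved, the calls also ended without limma's robust option (adjusted p = 0.734) and with a pseudocount of 0.01 FPKM (adjusted p = 0.70). Their ratio to each other stayed between 1.23 and 1.25 in all 6 libraries. The fourth locus did not separate the groups, at 13745, 13498 and 8574 FPKM in Ctrl and 6.17, 19613 and 6.48 FPKM in FPV. The sixth, intronic, stood at 6251, 6454 and 6951 FPKM in Ctrl and 12227, 0 and 10141 FPKM in FPV; a 0 at such a locus can be a failed estimate. Of the 53 loci with a mean of at least 100 FPKM, 6 were listed at 0 in at least 1 library.

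Among the 146 loci with a mean of at least 10 FPKM, every FPV library was above every Ctrl library at 15 and below at 32. Together these are 32.2% of the loci, where chance gives 10% on average for 3 against 3. Loci of a library can move together, so the share varies between splits. Other splits of the 6 libraries into 3 and 3 separated 6 to 26 of these loci, against 47 here, and 10 splits are too few for a test. The intergenic loci of this set (82) split into 10 above and 18 below, and the intronic ones (23) into 3 above and 4 below. Of the 15 loci with several positional codes, 0 stood above and 8 below, with a median log2 fold change of −0.91. Over all 146 loci the median was −0.05 (bootstrap 95% interval −0.25 to 0.22, from resampled loci and without the spread between flasks). The counts above and below became 6 and 9 with median-of-ratios scaling, 0 and 2 with upper-quartile scaling, and 28 and 31 with factors computed on these loci. Without Ctrl-2, FPV-1 or FPV-2 the count above was 30, 32 or 26, and the sets of 3 against 2 libraries overlap less by chance.

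No positional class passed the camera test against the other loci. Relative to the median of all tested loci, 0.03, the median log2 fold change was −0.04 for 24312 intergenic, 0.06 for 26215 intronic, −0.43 for 393 antisense, −0.49 for 166 exonic overlap and −0.11 for 325 shared junction loci. The adjusted p was 0.223 for antisense and exonic overlap loci and 0.912 for the other 3 classes at a preset correlation of 0.01, and 0.968 for each class as an adjusted p with an estimated correlation. The intergenic median and mean differed in sign before that subtraction, at −0.01 and 0.02. Antisense loci passed at an adjusted p of 0.0226 with a pseudocount of 1 FPKM, 0.0198 at a mean of at least 2 FPKM and 0.00367 without Ctrl-1, out of a range up to 0.731 over the alternatives. With an estimated correlation these 3 calls ended, at an adjusted p of 0.892, 0.577 and 0.776.

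A stretch of neighbouring locus numbers held many of the abundant intergenic loci and stood lower in infected cells. It was singled out after the values were seen, as the 500 consecutive numbers with the most loci of at least 10 FPKM (28, against 11 in the next such stretch). From number 136001 to 136500 it held 75 loci with a mean of at least 2 FPKM, all intergenic, of which 62 had lower and 13 higher mean log2 values in FPV. Every FPV library was below every Ctrl library at 30 of them and above at 1. Their median log2 fold change was −0.86 (bootstrap 95% interval −0.99 to −0.66), against −0.27 (−0.39 to −0.18) for the 542 other intergenic loci at that level. These intervals resample loci within the same 6 libraries, so they hold no spread between flasks. Without FPV-2 the medians were −0.80 and 0.05. The median of the stretch was −0.61, −0.88 and −0.77 with median-of-ratios, upper-quartile and abundant-loci scaling. The stretch held 5 of the 14 loci called lower. Without FPV-3 its median was −0.62 and that of the other intergenic loci −0.66.

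**Figure D3:**
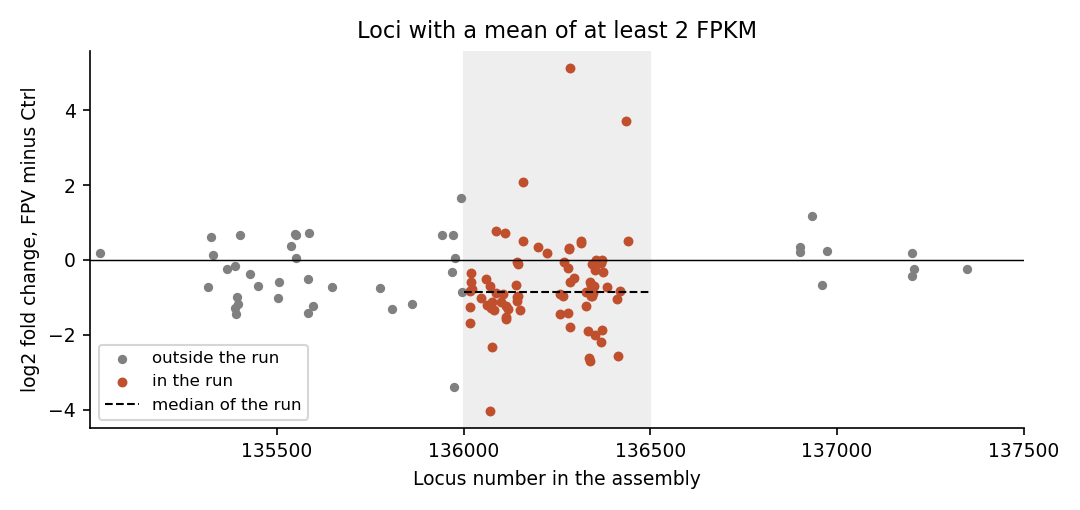
Log2 fold change (FPV minus Ctrl, log2(FPKM + 0.1) scale) of each locus with a mean of at least 2 FPKM against its number in the assembly, with the stretch from 136001 to 136500 shaded. The 75 loci of the stretch (red) have a median of −0.86 (dashed line), and 62 lie below 0.

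Some loci were listed in 1 group only. Above 0 in every FPV library and in no Ctrl library were 938 loci, and the reverse held for 1369. Other splits of the 6 libraries into 3 and 3 gave up to 1762 loci listed on 1 side only, so neither count exceeds what regrouped libraries give. Without FPV-3 these counts were 4310 and 1752, and without FPV-2 they were 1487 and 5036. The summed FPKM of the table was 203005 ± 10470 in Ctrl and 330378 ± 58810 in FPV (SD, n = 3 each), a ratio of 1.63. An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows, and 0.533 after Benjamini-Hochberg adjustment over 16 library measures. The ratio was 1.38 without the most abundant locus and 1.25 without the 10 most abundant. Loci with several positional codes held 0.879% ± 0.0754 of the sum in Ctrl and 0.539% ± 0.0574 in FPV (exact permutation p = 0.1, adjusted p = 0.533). As the sum itself was higher in FPV, this lower share does not show a lower level of these loci. The intronic share was 29.1% ± 3.04 and 28.9% ± 9.89 (exact permutation p = 1).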

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

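The settings chosen only after the data were seen were limma without robust alone, library weights, scaling on abundant loci, FPV-3 and Ctrl-1 left out together, and every setting for classes, abundant loci, detection and summed FPKM. Against 29 changed loci (15 higher, 14 lower, 22 by at least 1 on the log2 scale), the counts in that order were 2 (2, 0, 2) with a pseudocount of 1 FPKM, 41 (11, 30, 32) with 0.01 FPKM, 16 (5, 11, 13) without a filter and 4 (2, 2, 4) at a mean of at least 2 FPKM, where 3233 loci were tested. They were 47 (37, 10, 47) with median-of-ratios scaling, which moved the median of all loci from 0.03 to 0.19, 3 (3, 0, 3) with upper-quartile scaling and 28 (21, 7, 24) with scaling on abundant loci. With limma's trend and robust options off they were 0 (0, 0, 0), with a smallest adjusted p of 0.649; without robust alone they were 32 (19, 13, 32). Library weights, 5.08 for FPV-2 and 0.138 for FPV-3, gave 2814 (453, 2361, 2775). Each transcript on its own gave 29 (18, 11, 27). Leaving out 1 library gave 10 to 117 loci, 8 to 18 higher, 0 to 100 lower and 7 to 115 by at least 1; leaving out FPV-3 and Ctrl-1 together gave 36 (13, 23, 36). Of the 29 loci, 16 were also called with median-of-ratios scaling, 22 with scaling on abundant loci and 13 without FPV-3. The cause of these differences was not tested.

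The sample titles give replicate numbers without stating that they pair the flasks. With the group means removed, residuals of Ctrl and FPV libraries of the same number correlated at 0.046, −0.116 and 0.148. Those of different numbers correlated at −0.194 to 0.238. Residuals within a group depend on each other, so these values cannot settle a pairing. With the replicate number as a block the counts were 23 (17, 6, 21), with 14 loci shared, and the call on MSTRG.14336 ended (adjusted p = 0.108; 5.42e-25 to 0.926 over its alternatives). The calls on MSTRG.80310, MSTRG.119961, MSTRG.136072 and MSTRG.14336 held in 16, 9, 10 and 9 of 19 alternatives, and their directions in all 19.

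The abundant loci with FPV above or below Ctrl in every library (15 and 32) numbered 26 and 78 at a mean of at least 5 FPKM, 13 and 14 at 20 FPKM, 6 and 9 with median-of-ratios scaling, 28 and 31 with scaling on abundant loci, and 0 and 2 with upper-quartile scaling. Leaving out 1 library gave 17 to 32 above and 33 to 40 below. At a detection limit of 0.5 FPKM, 510 loci were listed in FPV only and 1789 in Ctrl only, against 938 and 1369; leaving out 1 library gave 1175 to 4310 in FPV only and 1752 to 5036 in Ctrl only, where fewer libraries have to meet the condition. The ratio of summed FPKM was 1.25 without the 10 most abundant loci. Among classes, intergenic and intronic medians changed sign between settings (−0.70 to 0.57 and −0.71 to 0.42). At a mean of at least 2 FPKM they passed camera, at −0.35 (adjusted p = 0.00334) and 0.20 (adjusted p = 0.000273), and exonic overlap loci passed with a pseudocount of 1 FPKM (adjusted p = 0.0226) and without Ctrl-1 (adjusted p = 0.00367). With an estimated correlation these 4 calls ended, at an adjusted p of 0.577, 0.577, 0.892 and 0.705. Without FPV-3 the medians at 2 FPKM were −0.70 for intergenic and −0.78 for intronic loci. Without any 1 of the other libraries they were −0.09 to 0.30 and 0.26 to 0.83, with loci chosen anew in each case. No alternative for coding genes or gene lists was run, as the table holds none, and DESeq2 was not run, as it holds no counts. The unknown depth leaves open how many of the zeros are sampling.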

Other observations

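All tests of explanations below were chosen after the result they address was seen. For the stretch of neighbouring numbers, first bounds for scaling (on the difference with all libraries alone) and for 1 library alone (on the median of the stretch alone) were met and counted against both. They were replaced by bounds on the difference with each library left out, once the value without FPV-3 had been seen. Below the most abundant loci and outside the stretch of neighbouring numbers, 4 more loci with means above 100 FPKM were called, each with a change under 1 on the log2 scale. A pair of intronic loci was at 262 ± 104 and 457 ± 122 FPKM in Ctrl and FPV (log2 fold change 0.85, limma adjusted p = 0.00102) and at 569 ± 220 and 977 ± 240 FPKM (0.83, limma adjusted p = 0.000467; SD, n = 3 each), with overlapping groups. Without Ctrl-1 the log2 fold changes of the pair were 0.509 and 0.506. The SD of the log2 ratio of this pair was 0.0349 over the 6 libraries, the second smallest of 2080 pairs, so its members are not separate evidence. An intergenic locus was at 329 ± 18.8 and 180 ± 39.9 FPKM (−0.89, limma adjusted p = 0.000582), and a locus with several positional codes at 146 ± 21.5 and 77.9 ± 32.6 FPKM (−0.98, limma adjusted p = 0.00199). These calls held in only 3, 5, 3 and 3 of 19 alternatives, in that order, and in 1, 3, 1 and 0 of the 6 fits that left out 1 library; without limma's robust option the adjusted p was 0.734 for each.

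Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split called 29 loci and the highest other split 10. It called 15 higher and 14 lower, against at most 9 in 1 direction elsewhere, and 22 by at least 1 on the log2 scale, against 9. It separated 47 of the abundant loci, against 26. In each of these counts, 1 of the 10 splits, the real one, reached the real value. For loci listed in FPV only (938) and in Ctrl only (1369), 7 and 5 of the 10 splits listed as many on 1 side, and the highest other split 1762. For the positional classes, of which the real split called 0 and another split 3, all 10 did.

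The second and the third most abundant loci stood higher together in FPV, in calls that ended without limma's robust option (adjusted p = 0.734). Scaling common to all loci would move the other abundant loci as much as the pair, which changed by 0.93 and 0.94. The median log2 fold change of the 146 loci of at least 10 FPKM was −0.0518, with an upper bound of 0.22. This argues against such scaling, but not against a shift shared by the most abundant loci only. Those ranked 1, 5 and 7 changed by 1.04, 0.49 and 1.06, and those ranked 4, 6 and 8 by −6.97, −4.82 and −0.07. The fall at rank 6 came from its 0 in FPV-2. Without FPV-2 the ratio of means, FPV to Ctrl, was 1.55, 1.09 and 1.60 at ranks 1, 5 and 7. At ranks 4, 6 and 8 it was 0.00053, 1.71 and 1.12. The limma calls on the pair ended with median-of-ratios scaling (adjusted p = 0.722 for each), at changes of 1.17 and 1.18. They also ended with upper-quartile scaling (adjusted p = 0.839 and 0.833), at 0.89 and 0.91. Reads shared between near-identical copies are a candidate explanation for the pair counting as 2 loci: the SD of their log2 ratio over 6 libraries was 0.0113, the smallest of 2080 pairs of loci of at least 50 FPKM, whose median was 1.40. The sixth locus kept a ratio of 0.424 to 0.429 to the second in the 5 libraries where it was above 0. Such copies would make the difference 1 event and not 2, and leave an effect of infection open, which was not tested apart from the groups.

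The stretch of 75 intergenic loci stood lower in FPV than other intergenic loci did. The median SD of log2 ratios between its loci was 0.95, and 0 of 2080 pairs had an SD under 0.05, so no pair kept a constant ratio. Noise at low FPKM can hide a constant ratio, so this cannot decide on shared reads of near-identical copies. With all libraries, 0 of 10000 sets of other intergenic loci matched for abundance had a median as low. The sets were drawn locus by locus, while loci of the stretch can move together, so this count cannot measure chance. Other splits of the 6 libraries gave the stretch a median of up to 0.54 in size, against −0.86 here. The stretch stayed below the other intergenic loci with median-of-ratios (−0.61 against −0.07) and upper-quartile scaling (−0.88 against −0.32). Without FPV-3 the difference was 0.0427 in place of −0.59, so it rested on FPV-3. That difference closed because the other intergenic loci moved from −0.27 to −0.66, while the stretch stood at −0.62. Both sets were chosen by a mean that includes FPV-3, which may have shaped their medians. Against the Ctrl mean, the median of the stretch was −0.57 in FPV-1, −0.47 in FPV-2 and −0.91 in FPV-3. A shift shared with other intergenic loci, such as scaling between libraries, cannot be told apart from a change of the stretch in FPV-1 and FPV-2. If assembly numbers follow the genome, the stretch may be a region with lower values in the FPV libraries, which is a hypothesis that coordinates and further flasks would test.

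At a mean of at least 2 FPKM, the median log2 fold change was 0.20 for 2310 intronic and −0.35 for 617 intergenic loci, 0.55 apart, and neither class passed camera with an estimated correlation (adjusted p = 0.577 for each). Without the stretch above they were still 0.47 apart, which argues against it as the source. Without FPV-3 both medians were below 0 and the difference was −0.0705, with loci chosen anew, and 0.04 over the same loci. The mean that selects these loci includes FPV-3, and without it 1057 intronic and 472 intergenic loci reached 2 FPKM. Selection on high FPV-3 values can therefore shape both medians. Over the same loci, leaving out any other library gave −0.41 to −0.10 for intergenic and 0.10 to 0.75 for intronic loci. With loci chosen anew these were −0.09 to 0.30 and 0.26 to 0.83, so the intergenic sign did not hold. Over the same loci the difference was lost only without FPV-3. Whether that is selection, technical or a difference in the infection of that flask was not tested.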
